A study of Mus musculus with 20 samples.

How the data were processed

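RNA was measured by poly(A)-selected RNA sequencing in 20 libraries that fall into 4 groups of 5. Per the labels, human hepatocellular carcinoma cell lines with TDO2 knocked down (KD) or overexpressed (OE), and their empty-vector controls (KD-NC and OE-NC), were injected under the skin of nude mice. The sample labels at the same time give the organism as Mus musculus and the tissue as liver, while the genes counted are human, so whether the libraries come from the tumours or from mouse liver is not settled by the labels. Groups and replicate numbers were taken from the sample titles. The labels name the lines MHCC-97H and Huh7 without tying either to an experiment, and they do not say whether libraries with different numbers came from different animals, so p-values measure the spread between these libraries.

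The count table holds raw read counts per gene, which the authors deposited beside 20 columns of counts normalised with edgeR that were not used here. Per the submitters' processing notes, reads were handled with cutadapt, FastQC, HISAT2, StringTie and edgeR, with the mouse build mm10. The count table, per the file headers, lists human Ensembl gene identifiers, so the build named in the notes and the genes counted disagree, and which genome the reads were aligned to was not settled. No coordinates are given for that reason. The table held 17300 genes with values. The authors' deposited comparison tables give log2 fold changes, log2 CPM, p-values and false discovery rates, and the tables of called genes were filtered at a fold of 2 and a p-value of 0.05, per the file headers. Values from these tables are named as the authors' wherever they are printed.

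Each comparison was fitted on its own 10 libraries with edgeR 4.0.16 in R 4.3.3 (TMM scaling, the default expression filter, the quasi-likelihood F test, two-sided, Benjamini-Hochberg adjustment, threshold adjusted p of 0.05). The difference between the OE and KD effects was an interaction contrast over all 20 libraries. The design had been written for either FPKM or counts, and the deposited counts led to the count test. Level limits set in FPKM were replaced by CPM: a gene needed a mean of 1 CPM to be named, and the stricter filter asked for 1 CPM in at least 5 libraries. Levels are TMM-normalised CPM, as mean ± SD. The standard error of a log2 fold change was derived from the fold change and its F statistic. Single values were compared with exact two-sided permutation tests over 252 assignments, whose smallest possible p is 0.00794.

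Before the data were examined, 37 gene lists, the rule for named genes and the alternatives were fixed. The named genes were TDO2, ADCY5 and PRKAR2B, then in each direction the 10 genes past the threshold with the largest change, with open places filled by the smallest raw p and described as not past the threshold; for the difference of effects it was 5 per direction. Up to 4 members with the smallest raw p were named per list described. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at its preset inter-gene correlation of 0.01. List symbols, written as mouse genes, were matched to the human symbols without regard to case, which placed 486 of 595 distinct members. The rule fixed beforehand also sent older symbols through a reference table where one is given. The table at hand holds mouse synonyms, some of which point to unrelated human genes, and that part of the rule was not applied in the main test, which therefore departs from the rule as fixed. With it 500 members were placed, and with a hand-made map to human names (29 entries) 511 were. The map was written after the list results had been seen and served for a time as the main match, and the return to matching by case was settled after the counts under matching by case and under the map were known. The choice moves the number of lists past the threshold, so all 3 counts are printed with the results.

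On counts simulated from these libraries, the KD fit recovered 22.4% of genes changed 1.5-fold, 65.7% of those changed 2-fold and 98.5% of those changed 4-fold, with 11 false calls among 12413 unchanged genes. For the OE comparison the same shares were 70.1%, 83.6% and 100%, with 8 false calls among 12506. The camera step recovered a list shifted 1.5-fold in both simulations and called no other list. Genes were drawn independently in these simulations, so the recovery shares and false calls hold only without correlation between genes. Each gene was also given the dispersion of the trend at its level, and no library was made to stand apart. The recovery shares may therefore be too high for the real libraries. The real libraries behaved otherwise for lists. Among 100 splits of them per comparison, the real groups included, 80 other splits in KD and 95 in OE called at least 1 list (medians 3 and 5).

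Alternatives covered the expression filter, median-ratio scaling, quantile scaling (fitted with limma on log2(CPM + 1), so scaling and test change together), the pseudocount (limma on log2 CPM), sample weights (limma voom), a block for the replicate number, a fit of all 20 libraries, DESeq2 1.42.0, the authors' thresholds, camera with an estimated correlation, fry, and leaving out each library in turn. A limma fit on log2(CPM + 1) and a correction for transcript length and GC content were added after the data had been seen. The correction used the longest coding transcript of the mouse gene of the same name, found for 85.9% of tested genes in the KD comparison and 85.7% in the OE comparison. Libraries within a group differed by far more than sampling noise (mean chi-square per gene of 11.7 or more for every pair), so none was treated as a repeat deposit. Figures were drawn with matplotlib 3.10.9.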

Results

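The libraries held between 15.6 M and 30.3 M counts and detected between 13771 and 14788 genes each. KD libraries averaged 23.4 ± 3.08 M counts, KD-NC 22.8 ± 4.37, OE 26.1 ± 4.04 and OE-NC 22.7 ± 3.18 (SD, n = 5 each). Across the 190 library pairs, log2 CPM correlated with r between 0.936 and 0.985, and pairs from different experiments had a median r of 0.967. Some epithelial and hepatic genes were high and others low or nearly absent. The keratin gene KRT18 stood at 1018 ± 147 CPM, the albumin gene ALB at 671 ± 143, the cadherin gene CDH1 at 100 ± 16.9 and the alpha-fetoprotein gene AFP at 27.8 ± 5.63 (SD, n = 20). The apolipoprotein gene APOA1 stood at 0.814 ± 0.632 CPM, the transthyretin gene TTR at 6.08 ± 2.23, the liver tumour marker GPC3 at 0.0345 ± 0.0595 and the epithelial gene EPCAM at 2.24 ± 0.958 (SD, n = 20). The fibroblast collagen COL1A1 stood at 0.057 ± 0.09 CPM and the leukocyte gene PTPRC at 0.276 ± 0.412 CPM (SD, n = 20). The 18 hepatocyte markers counted had a median of 5.28 CPM and the 12 macrophage and Kupffer cell markers 0.12. For the 23 proliferation genes the median was 85.2 CPM. The low hepatocyte and macrophage medians argue against whole liver as the source, though ALB and the macrophage marker SPP1 (2039 CPM) were high.

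**Figure D1:**
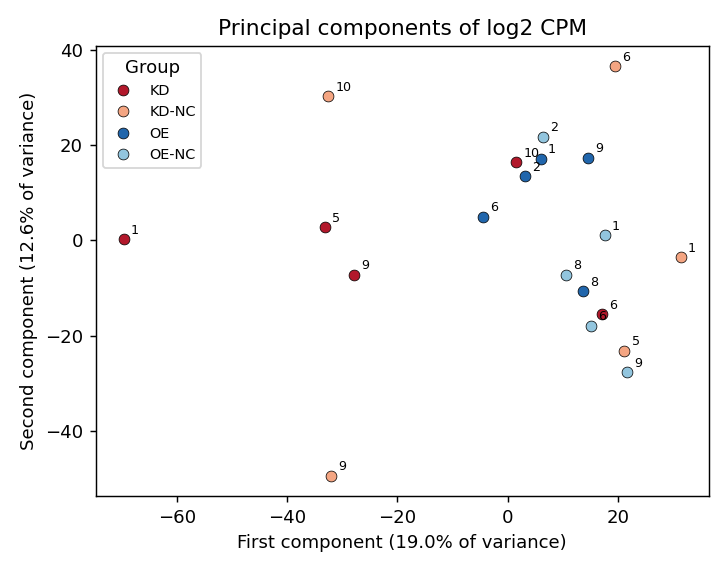
Each point is 1 library placed on the first (x axis) and second (y axis) principal component of log2 CPM, coloured by group and numbered by replicate. The components hold 19.0% and 12.6% of the variance, KD replicate 1 lies farthest to the left at -69.7, and the 4 groups overlap.

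The first question was whether the manipulated gene differed between the groups. TDO2 (ENSG00000151790), which encodes the tryptophan-degrading enzyme tryptophan 2,3-dioxygenase, was counted in all 20 libraries with 239 to 524 reads each. It averaged 18.7 ± 4.09 CPM in KD and 17.8 ± 3.68 in KD-NC, and 15.3 ± 1.75 in OE and 17.4 ± 1.94 in OE-NC (SD, n = 5 each). The log2 fold change was 0.06 in KD (95% interval -0.36 to 0.47) and -0.18 in OE (95% interval -0.43 to 0.08). Exact two-sided permutation tests gave p = 0.706 for KD and p = 0.127 for OE. Both intervals exclude a halving in KD and a doubling in OE, so in these counts the libraries labelled KD and OE did not carry a change of that size in TDO2, and directions drawn from those labels rest on the labels alone.

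**Figure D2:**
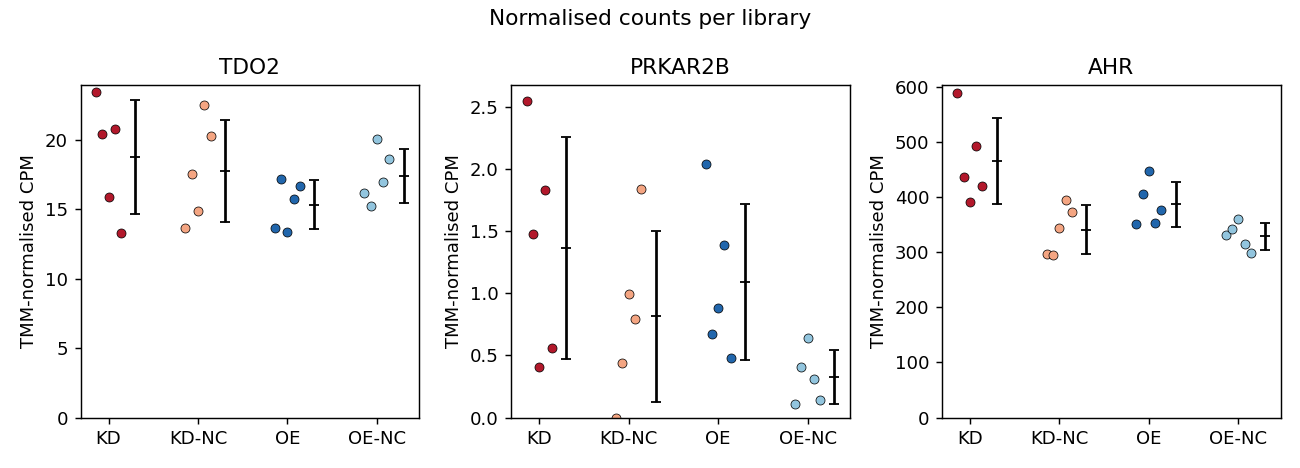
TMM-normalised CPM (y axis) of TDO2, PRKAR2B and AHR in each library, with points for the 5 libraries of a group and black bars for the mean and SD. TDO2 lies between 13.3 and 23.4 CPM in all 20 libraries, and the groups overlap.

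The series design also names ADCY5 (ENSG00000173175), an adenylyl cyclase that makes cAMP, and PRKAR2B (ENSG00000005249), a regulatory subunit of protein kinase A. ADCY5 had 3 reads in total over the KD libraries, 2 over KD-NC, 14 over OE and 1 over OE-NC, too few for a fitted fold change; the largest count in a single library was 10, in OE. The exact permutation test of its CPM gave p = 0.881 in the KD comparison and p = 0.286 in the OE comparison. PRKAR2B averaged 1.36 ± 0.895 CPM in KD and 0.815 ± 0.687 in KD-NC (SD, n = 5; exact p = 0.31). It averaged 1.09 ± 0.629 CPM in OE and 0.324 ± 0.217 in OE-NC, with 4 of 5 OE libraries above every control (SD, n = 5; exact permutation p = 0.0159). Adjusted over the 6 permutation tests of these genes, that p became 0.0952, and the edgeR log2 fold change of 1.69 ± 0.54 (SE) had an adjusted p of 0.691. In the authors' deposited table PRKAR2B had a log2 fold change of 1.71 with p = 0.0301 and a false discovery rate of 1, and ADCY5 had 3.09 with p = 0.0412 and a false discovery rate of 1.

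In KD against KD-NC, no single gene passed the threshold, and 2 gene lists did. They were ribosomal proteins, lower in KD, and inflammatory cytokines and chemokines, higher in KD. That number does not set the groups apart: 70 of 100 splits of these libraries, the real one included, called at least 2 lists (median of the others 3). Both list calls also depend on the preset correlation between genes in camera, and each list had an adjusted p of 0.802 with an estimated correlation. Of 20 ribosomal protein genes 19 were lower in KD, with a median log2 fold change of -0.19. Of 13 inflammatory genes 10 were higher, with a median of 0.34; the chemokine genes CXCL5 (1046 against 726 CPM) and CXCL2 (131 against 95.9 CPM) and the prostaglandin synthase gene PTGS2 (234 against 154 CPM) were among them, none past the test on its own. Camera gave the ribosomal list an adjusted p of 0.00143 and the inflammatory list 0.0479 among 27 lists. The inflammatory call was lost when KD replicate 5 (adjusted p = 0.0956), KD replicate 6 (median 0.20, adjusted p = 0.335), KD replicate 9 (0.11), KD-NC replicate 6 (median 0.18, adjusted p = 0.399) or KD-NC replicate 10 (median 0.10, adjusted p = 0.708) was left out, and the ribosomal call without KD-NC replicate 9 (median -0.11, adjusted p = 0.434). The inflammatory median was 0.66 without KD-NC replicate 5 and 0.58 without KD-NC replicate 9, and the ribosomal median was -0.12 without KD replicate 1. The ribosomal call was also lost with limma's sample weights (median -0.145, camera adjusted p = 0.116) and with a length and GC trend removed (median -0.0725, camera adjusted p = 0.202). Fits with limma gave larger inflammatory medians and yet lost the call: 0.49 on log2(CPM + 1) (adjusted p = 0.076), 0.57 with quantile scaling added (0.0614), 0.60 with a pseudocount of 0.1 (0.0751) and 0.63 with sample weights (0.522). The number of lists was 4 without KD-NC replicate 1 and 5 without KD-NC replicate 5. It was 2 with reference synonyms for list members and 1 with human names, where the inflammatory list had an adjusted p of 0.0515.

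edgeR tested 12754 genes in this comparison. None had an adjusted p under 0.05 (smallest 0.816), and DESeq2 and limma also called 0. At a raw p under 0.05 there were 561 genes (334 higher and 227 lower in KD). A share of 0.05 of the genes tested gives 638 by chance, while other splits of these libraries had a median of 279. The genes with the smallest raw p, none past the threshold, included TMTC3 at 100 ± 15.2 CPM in KD and 67.2 ± 8.69 in KD-NC, GULP1, an engulfment adaptor, at 194 ± 40 against 128 ± 21.6, and GCLM, the modifier subunit of the glutathione-synthesis enzyme, at 1053 ± 165 against 776 ± 54.2 (SD, n = 5 each). In each of these, all 5 KD libraries lay above every control. LCA5, PTPN14, CDS1, DEPDC1, LRRC8B and SCIN had log2 fold changes of 1.18, 0.64, 0.77, 0.53, 0.49 and 0.57. AHR, the aryl hydrocarbon receptor that kynurenine can activate, stood at 466 ± 78 CPM in KD and 341 ± 44.8 in KD-NC (log2 fold change 0.43 ± 0.13 SE, edgeR adjusted p = 0.816). Adjusted over the list alone, 1 of the 8 tested genes of the receptor list was past 0.05 (0.0417). It was the only such gene among the 27 lists tested. The receptor list itself was not called (median -0.0041, 5 of 8 lower, camera adjusted p = 0.485), nor was the tryptophan-kynurenine list (camera adjusted p = 0.965). On the lower side, NISCH stood at 14.3 ± 1.16 against 20.7 ± 2.29 CPM, INHBB, an inhibin subunit, at 29.5 ± 4.08 against 41.9 ± 7.38, and STC2, a secreted glycoprotein, at 12 ± 1.71 against 17.3 ± 2.11 (SD, n = 5 each). FOXD4, LRRC39, C1orf74, CDPF1, PIDD, PPM1N and KIF12 had log2 fold changes of -1.58, -1.82, -0.93, -0.80, -1.05, -0.85 and -0.86. Biological variation in this comparison was 28.7%. The number of genes at a raw p under 0.05 was 181, 350 and 278 without KD replicates 1, 5 and 9, 216 and 254 without KD-NC replicates 1 and 5, 1148 without KD replicate 6, and 1089 and 1129 without KD-NC replicates 9 and 10. It was 973 with no expression filter, 1419 with all 20 libraries fitted together and 2698 with limma's sample weights, the last 2 well above the number expected by chance, and still no gene passed (smallest adjusted p 0.403 with all 20 and 0.186 with weights).

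In OE against OE-NC, 4 gene lists were lower in OE under each way of matching list symbols, 2 more were lower with symbols matched by case alone, and none was higher. The symbol rule fixed beforehand, which includes reference synonyms, gives the 4, and the main test, which left the synonyms out, gives 6. None of the 6 calls held with an estimated correlation between genes, where each had an adjusted p of 0.599. Of 100 splits of these libraries, the real one included, 45 called at least 6 lists (median of the others 5). All 14 tested inflammatory genes were lower, with a median log2 fold change of -0.45; the granulocyte growth factor CSF3 stood at 1.79 against 4.33 CPM and TGFB1 at 42.5 against 51.6 CPM. Of 18 glycolysis and hypoxia genes 17 were lower, with a median of -0.23; the glucose transporter SLC2A1 stood at 185 against 250.2 CPM, the stress gene NDRG1 at 736 against 1067 and the angiogenic factor VEGFA at 439 against 594. Of 17 matrix genes 15 were lower, with a median of -0.18, among them the collagen crosslinking enzyme LOX at 19.7 against 37.7 CPM. Ribosomal proteins (median -0.16, 19 of 20 lower), bile duct cell markers (median -0.14, 8 of 9 lower, with MUC1 at 6.39 against 10.9 CPM) and nuclear-encoded respiratory chain genes (median -0.10, 15 of 18 lower) followed. No member of these lists passed the test on its own.

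Among 25 lists, camera gave adjusted p = 4.78e-05 for the inflammatory list and for the glycolysis and hypoxia list, 0.00171 for ribosomal proteins, 0.00229 for matrix genes, 0.0486 for bile duct markers and 0.0496 for respiratory chain genes. Without OE replicate 9 the inflammatory and matrix lists were no longer past the threshold (medians -0.28 and -0.11, adjusted p = 0.0666 each). The inflammatory median was -0.19 without OE-NC replicate 6 and -0.67 without OE-NC replicate 2. OE-NC replicate 9 carried nearly all of the ribosomal and respiratory chain shifts: without it the ribosomal median was -0.0147 (adjusted p = 0.803) and the respiratory chain median 0.0041, while the bile duct median was -0.07. Quantile scaling fitted with limma, which changes the test as well as the scaling, gave the glycolysis and hypoxia list a median of -0.13, still past the threshold, and the ribosomal list -0.08 (adjusted p = 0.081). The bile duct list was lost without OE replicate 1 (adjusted p = 0.138), 2 (0.09), 6 (0.118) or 9 (0.0553) and without OE-NC replicate 1 (0.0588), 8 (0.106) or 9 (0.144). The respiratory chain list was lost without OE replicate 1 (adjusted p = 0.184), 2 (median -0.06, adjusted p = 0.244) or 6 (0.118) and without OE-NC replicate 9 (0.827), and its median was -0.17 without OE replicate 8. It was also lost when a length and GC trend was removed (median -0.02, adjusted p = 0.472). The number of lists was 3 without OE replicate 9, 12 without OE replicate 8 and 10 without OE-NC replicate 2. These 2 lists also depend on how symbols are matched: with reference synonyms, as the rule fixed beforehand asked, the bile duct and respiratory chain lists had adjusted p of 0.0506 and 0.0516, with human names 0.0525 and 0.0536, and 4 lists remained past the threshold in either case.

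edgeR tested 12813 genes in OE against OE-NC. None had an adjusted p under 0.05 (smallest 0.691), and DESeq2 and limma also called 0. At a raw p under 0.05 there were 906 genes (488 higher and 418 lower in OE). A share of 0.05 of the genes tested gives 641 by chance, while other splits of these libraries had a median of 509. The genes with the smallest raw p, none past the threshold, included on the higher side SYNJ2BP at 15.9 ± 2.64 CPM in OE and 10 ± 1.43 in OE-NC, PRR14L at 68.8 ± 5.01 against 51.1 ± 6.49, POLQ, a DNA repair polymerase, at 65.1 ± 4.69 against 47.8 ± 6.88, and NKTR at 182 ± 11 against 142 ± 14.6 (SD, n = 5 each). ZKSCAN8, PEAK1, ZNF510, ZNF281, ZNF891 and PHLPP2 had log2 fold changes of 0.54, 0.46, 0.44, 0.39, 0.59 and 0.63. On the lower side, the growth factor PDGFB stood at 15 ± 1.73 against 23.5 ± 6.18 CPM, PRDM1, a transcriptional repressor, at 5.41 ± 1.52 against 9.81 ± 2.62, PMEPA1 at 103 ± 8.02 against 131 ± 15.1, and SCD5, a fatty acid desaturase, at 9.28 ± 2.8 against 15.4 ± 2.56 (SD, n = 5 each). SCUBE1, PTOV1, RNF183, C1orf115, RASSF2 and ALS2CL had log2 fold changes of -0.76, -0.35, -0.70, -0.38, -0.82 and -0.61. AHR had a log2 fold change of 0.24 ± 0.08 (SE), with 387 ± 40.7 CPM in OE and 329 ± 24.3 in OE-NC (SD). The edgeR quasi-likelihood test gave AHR in OE a raw p of 0.0133 and a Benjamini-Hochberg adjusted p of 0.691, and adjusted over the list alone it was not past 0.05 either (0.107). Biological variation was 17.1%. The number of genes at a raw p under 0.05 was 1605 without OE-NC replicate 2, 1515 with limma's sample weights and 309 with all 20 libraries fitted together. With all 20, OE thus had fewer such genes than expected by chance and KD more, the reverse of the separate fits.

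The third comparison asked whether the OE effect differed from the KD effect. Only the inflammatory list passed the threshold, with a median of 0.34 in KD, -0.45 in OE and -0.68 for the difference (camera adjusted p = 4.18e-05 among 27 lists, adjusted p = 0.754 with an estimated correlation). That call does not set the list apart from chance. Of 100 regroupings of the libraries, the real one included, 49 put this list past the same threshold. No single gene passed. Among 13285 genes tested with edgeR the smallest adjusted p was 0.999, and limma called 0. At a raw p under 0.05 there were 390 genes, where 0.05 of the genes tested is 664. Other regroupings of the libraries had a median of 371, so 390 is a usual number here. The number at a raw p under 0.05 was 657 and 714 without KD replicates 6 and 10, and 956 and 612 without KD-NC replicates 9 and 10, and 776 with no expression filter. The genes with the smallest raw p included the hypoxia regulator VHL (log2 fold change -0.26 in KD and 0.43 in OE), RASSF2 (0.56 and -0.82), CCDC121 (0.60 and -0.35) and FOXD4 (-1.58 and 0.03). KIAA1919, DFFA, HECW1, TRIM23, AAED1 and FAM3C had differences of 0.98, 0.42, 0.75, -0.61, -0.53 and -0.40. TDO2 had a difference of -0.25 ± 0.23 (SE).

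In the refit, more genes shared a sign between the comparisons than differed, which did not hold for the genes the authors call. Across 12593 genes, the log2 fold changes of KD and OE correlated with Pearson's r = 0.183 and Spearman's rho = 0.271, and 62.1% shared a sign. Pearson's r was 0.0102 with no expression filter and between 0.10 and 0.24 with single libraries left out. Genes are not independent replicates, and the comparisons share no library. Of the genes with a raw p under 0.05 in both, 36 were higher in both where 12.8 would be expected from the list sizes, 17 were lower in both (7.33 expected), 1 was higher in KD and lower in OE (10.9 expected) and 0 were lower in KD and higher in OE (8.59 expected). LRRC8B, TMTC3, BRCA2, AHR and RAB27B led the genes higher in both, chosen here by their p after the values were seen. Of 100 regroupings of the libraries, 18 gave a Pearson's r as large in size. Fold changes also correlated with transcript length in the same direction in both comparisons (Spearman's rho 0.27 in KD and 0.257 in OE). Such a shared trend could contribute to the shared signs and overlaps, and the relation was not rerun with it removed.

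The authors' deposited tables call genes at an unadjusted p. In KD they list 771 genes (325 higher and 446 lower) and in OE 421 (189 higher and 232 lower), while 0 of 16452 and 0 of 16813 genes in the authors' deposited table had a false discovery rate under 0.05. At a p under 0.05 the authors' deposited tables hold 2137 genes in KD, where 823 would be expected by chance, and 622 in OE, where 841 would be. The separate refits lie the other way, and the fit of all 20 libraries (1419 and 309) lies the same way as the authors' tables. The authors' tables give AHR the same log2 CPM of 8.57 in both comparisons, which points to a fit of all libraries together. Biological variation was 28.7% in KD and 17.1% in OE when fitted apart, and 24.3% over all 20. The excess in KD thus depends on which libraries share a fit and is not by itself a sign of a KD effect. Of the genes the authors' deposited table calls, 91.7% in KD and 94.8% in OE lay below 1 CPM, and 545 and 308 had no read in 1 of the groups compared. In the refit 84 and 38 of them passed the expression filter, all with the same direction, 52 and 38 had a raw p under 0.05, and 0 were past the adjusted threshold. The authors' deposited tables call 40 genes in both comparisons (18.8 expected from the list sizes), 20 in the same direction and 20 in opposite directions.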

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

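The tests of TDO2, of the control groups and of other splits of the libraries were chosen or written down after the values they measure had been seen; those of the length and GC trend were written before.

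Of 106 groups of 5 libraries examined, 5 held a library far from the others, where chance gives about 5.3. The gap of that library to its nearest neighbour was a share of 0.852 of the range for GULP1 in KD replicate 1 (265 CPM, others 170 to 184), 0.741 for CDPF1 in KD-NC replicate 10 (9.8 CPM, others 5.42 to 6.56), 0.716 for PEAK1 in OE replicate 9 (59.4 CPM, others 75.8 to 82.3) and 0.748 for RASSF2 in OE-NC replicate 6 (10.1 CPM, others 5.63 to 6.76). ADCY5 had a share of 1 in OE-NC replicate 9, the only library of its group with a read.

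The inflammatory list differed between the OE and KD effects by a median of -0.68. Chance cannot be excluded: of 100 regroupings of the libraries within the experiments, 35 gave this list a median difference as large in size (real 0.68, highest other 1.79). For the number of lists that differ, 82 of 100 reached the 1 observed (highest other 13). The 2 lists of the KD comparison were matched by 70 of 100 splits (highest other 10), and the 6 lists of the OE comparison by 45 of 100 (highest other 15).

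Some of the lists may follow a technical trend between libraries, since fold changes correlated across genes with transcript length (Spearman's rho 0.27 in KD and 0.257 in OE). With a length and GC trend removed per library, the members of the glycolysis, inflammatory and matrix lists kept a median of -0.27 in OE (-0.27 before), which argues against that trend as their cause. The ribosomal list moved from -0.19 to -0.0725 in KD, where it lost its call (adjusted p = 0.202) because the shift shrank, and from -0.16 to -0.0816 in OE (adjusted p = 0.0177), so for these genes trend and biology cannot be told apart. The respiratory chain list, for which no prediction had been written, moved from -0.10 to -0.02 in OE and lost its call (adjusted p = 0.472). The inflammatory list in KD, also without a prediction, kept its size and its call (median 0.33 from 0.34, adjusted p = 0.00859), which argues against the trend as its cause. AHR kept a log2 fold change of 0.30 ± 0.09 (SE) in KD, from 0.43 ± 0.13, and of 0.17 ± 0.06 in OE, from 0.24 ± 0.08. Both values stayed above 0.5 times their earlier size, so the trend does not account for all of the AHR shift by these estimates. The KD value is within its error of 0.5 times its earlier size, so part of the shift stays open to the trend.

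TDO2 at like levels in all groups could come from swapped labels or from low depth. The highest library had 1.77 times the TDO2 CPM of the lowest, so no exchange of labels among the 20 libraries yields groups that are 2-fold apart. The intervals end at -0.36 in KD and 0.0761 in OE, so depth was not the limit. Loss of the manipulation in the tumours, a construct not counted as the gene, or libraries other than those labelled were not tested.

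No gene differed between the KD-NC and OE-NC groups in edgeR (0 of 12780, 781 at a raw p under 0.05, 639 expected), though the labels name MHCC-97H and Huh7. Of 11986 genes above 1 CPM, 1 was 4-fold apart. Libraries of different experiments correlated with a median r of 0.967, against 0.96 within the KD experiment and 0.978 within the OE experiment. These values argue against a different line in each experiment, unless the 2 lines differ at few genes. How many genes part the named lines was not measured here, so which line was used stays open.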

How the results depend on the processing

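The limma fit on log2(CPM + 1), the length and GC correction and the map of list members to human names were added after the data had been seen. Reference synonyms belong to the symbol rule fixed beforehand but were run after the counts for the other matches had been seen. No gene passed the adjusted threshold in KD, OE or the difference under any alternative run, including each library left out; the authors' thresholds on the refit gave 55 genes in KD and 76 in OE by construction, since they use an unadjusted p. The 2 KD lists became 1 with no expression filter, quantile scaling fitted with limma, a pseudocount of 0.1, all 20 samples fitted, limma on log2(CPM + 1), the length and GC correction and human names for members, and 0 with sample weights, an estimated correlation and fry; leaving out single libraries gave 1 to 5. The 6 OE lists became 3 with quantile scaling fitted with limma, where limma on log2(CPM + 1) without it gave 4, and also 4 with no expression filter, median-ratio scaling, a pseudocount of 0.1, and all 20 samples fitted, 8 with sample weights, and 0 with an estimated correlation and fry; leaving out single libraries gave 3 (without OE replicate 9) to 12 (without OE replicate 8), and 10 without OE-NC replicate 2. Matching through human names gave 1 list in KD and 4 in OE, against 2 and 6 for matching by case, and reference synonyms gave 2 and 4, so the bile duct and respiratory chain calls in OE hang on a choice settled after the counts for case and human names had been seen. The lists for bile duct markers, respiratory chain genes and, in KD, inflammation were each lost under 5 of the alternative fits fixed beforehand, and respiratory chain genes under the length and GC correction as well. Glycolysis and hypoxia kept its call in all 10 alternative fits and with each library left out, though not with an estimated correlation or fry. The correlation of KD and OE fold changes fell to 0.0102 with no expression filter, which adds genes of few reads, and lay between 0.10 and 0.24 with single libraries left out. TDO2 in KD turned to -0.14 with the length and GC correction and lay between -0.0368 (without KD replicate 1) and 0.16 with single libraries left out, never near the threshold. Except where stated, the cause was not tested.

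The replicate numbers were not taken to pair the libraries, which would have asked for r over 0.1 in every pair. Deviations of same-numbered libraries correlated with r between -0.28 and 0.07 in KD (0 of 5 over 0.1) and between 0.07 and 0.12 in OE (3 of 5 over 0.1, all positive), and 1 of 5 and 2 of 5 correlated best with their own number, so a weak link in OE is not excluded. With the number as a block, 0 genes passed in KD and 0 in OE (277 and 1406 at a raw p under 0.05, smallest adjusted p 0.903 and 0.201), and 2 and 6 lists did. The inflammatory list in KD had a median of 0.60 in that fit and kept its call (adjusted p = 5.89e-05).

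Chance cannot be excluded for the counts of genes at a raw p under 0.05. The other splits had medians of 279 in KD and 509 in OE, and the other regroupings 371 for the difference. Each is below 0.05 of the genes tested, so that share overstates what a usual split of these libraries gives. Splits of the same libraries gave as many genes at a raw p under 0.05 as the 561 in KD in 29 of 100 (highest other 5371) and as the 906 in OE in 24 of 100 (highest other 2740); for the difference, 49 of 100 regroupings reached 390 (highest other 2777). For the 0 genes past the threshold the splits decide nothing, since any split reaches 0 (100 of 100 in each case, highest other 3809, 544 and 1). For the correlation it was 18 of 100 (highest other 0.403).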

Other observations

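All tests here were chosen after the data had been seen, apart from the prediction for the length and GC trend.

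The inflammatory list and the glycolysis and hypoxia list moved together from library to library. Over the 20 libraries their mean standardised levels correlated with Pearson's r = 0.825 (permutation p = 1e-05, the smallest the resampling can give; adjusted 3e-05 over 3 relations) and Spearman's rho = 0.866 (permutation p = 2e-05, adjusted 6e-05). Without OE replicate 9 and KD-NC replicate 10, r was 0.792. Within the KD experiment r was 0.811 and within the OE experiment 0.853 (n = 10 each). The lists share 0 tested members.

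AHR followed the length trend of a library, the rank correlation across genes of its deviation from the mean with transcript length. Over the 20 libraries Pearson's r was 0.776 (permutation p = 8e-05, adjusted 0.00012) and Spearman's rho 0.752 (permutation p = 0.0002, adjusted 0.0003). Without OE-NC replicate 9 and KD replicate 1, r was 0.689, and it was 0.868 within the KD experiment and 0.807 within the OE experiment. The trend is computed over all genes with a known length, so long transcripts tend to follow it by construction. How many other genes follow it as closely was not measured, so these values show no relation particular to AHR. AHR and TDO2 correlated with r = 0.354 (permutation p = 0.124, adjusted 0.124) and rho = 0.25 (permutation p = 0.286, adjusted 0.286), with r of 0.561 within the KD experiment, -0.443 within the OE experiment and 0.107 without KD replicate 1 and KD-NC replicate 9.

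A split of the KD experiment that ignores its groups had KD replicates 1, 5 and 9 and KD-NC replicates 9 and 10 on one side. It called 3809 genes past the threshold. This split was picked because it called the most genes of 100 splits, and no other split called any. The count therefore describes how these libraries part most strongly and is not a test of a structure among them. A length and GC trend may account for part of the 3809 calls: with the trend removed the same split called 953, between the bounds set for a whole cause and for none, so what remains cannot be told apart from other differences between libraries.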
